A study of Homo sapiens with 8 samples.

How the data were processed

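The series compared C4-2 human prostate cancer cells that carried a control short hairpin RNA (shCTRL) with cells that carried a hairpin against CDCA8 or against EZH2. PolyA RNA was sequenced from 2 shCTRL and 2 shCDCA8 libraries, and small RNA from 2 shCTRL and 2 shEZH2 libraries, 8 libraries in 4 groups. Per the labels' protocols, libraries were made and sequenced by BGI on the DNBseq platform after extraction with Qiagen kits, and the same labels also describe a Zymo extraction with Illumina library preparation without saying which libraries it covers. The submitters' processing notes name TopHat, HTSeq, edgeR and cutadapt and the genome build hg19, without versions and without saying which tool was used on which table. The annotation and the microRNA reference are not given in the sources used here.

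The deposited values are RPM, reads scaled to a fixed library total, per the file names and column headers, in a table of 18892 genes and a table of 1506 small RNA features. How the authors chose the number of reads that each library was divided by is not given in the sources used here. Every value was a whole multiple of a fixed step in its library (100% of values above 0 within 0.01 of a whole read), so the divisor and the whole reads could be recovered. The divisor was larger than the sum of the rows in all 8 libraries, so RPM moves with the share of reads that fall outside the rows analysed here. No column of another sample was in either table, and no row lacked a feature name.

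Values were tested as log2(RPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend, two-sided), and a fold change is on this scale, which understates the change of low genes. Genes with at least 1 RPM in at least 2 of 4 libraries (11833) and small RNA features with at least 5 RPM in at least 2 of 4 libraries (241) were kept. A call is a Benjamini-Hochberg adjusted p under 0.05 over all kept features of a table, and "rose" or "fell" is used only of calls. Because both tables moved as a whole, the main counts are also given after each library was divided by its median ratio to the geometric mean of the 4 libraries (median-ratio scaling). The unit differs from counts, so count models served only as alternatives: edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads, where edgeR called 7807 genes and 0 small RNA features.

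Before the data were examined, 23 gene lists and 16 microRNA lists were written down, together with the tests, most alternatives and the rule for named genes. Lists with at least 3 kept members (19 and 12) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a table, and fry was run beside it. The gene lists were the chromosomal passenger complex, mitotic genes, DNA replication and E2F target genes, cholesterol synthesis, ATF4 target genes, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kB and inflammatory genes, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, immediate early and heat shock genes, epithelial genes, mesenchymal transition genes, neuroendocrine genes, published let-7 targets, Polycomb repressive complex 2, and markers of fibroblasts, of basal epithelium and of leukocytes and endothelium; 2 further lists, both tested, are not described here. The microRNA lists were the let-7, miR-200, miR-34, miR-15/16, miR-29 and miR-30 families, the miR-17-92, miR-23/27/24, miR-183/96/182, miR-221/222, 14q32 and chromosome 19 clusters, published Polycomb-repressed, EZH2-targeting and androgen-responsive microRNAs, and microRNAs of other cell types. Older symbols were matched through the gene name tables.

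The genes named in the text are CDCA8, EZH2, E2F1, AURKB, BIRC5, INCENP, KLK3 and CDKN1A, the 10 largest rises and 10 largest falls among calls with a mean of at least 5 RPM, a gene symbol other than a clone or locus number and no overlap between the groups, and the 3 members of each list with the smallest p (1 where fewer than 3 were called). In the small RNA table they are the kept let-7 features, up to 8 rises and 8 falls with a mean of at least 50 RPM chosen the same way, filled to 5 by smallest p, 1 member per list, the 5 most abundant features and every call. Genes named outside this rule are said to be so, and some genes under the rule are not described here.

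The fit was tested on simulated data with known changes. Over 11609 simulated genes it recovered 57.8% of 1.5-fold, 87.7% of 2-fold and 100% of 4-fold changes, and called 7 of 11416 unchanged genes. Over 231 simulated small RNA features it recovered 7.14%, 46.2% and 100% of such changes and called 0 of 193 unchanged features. The simulation gave features of similar abundance the same spread and added no shift between groups. Its rates of false calls therefore need not hold for these tables. The 2 libraries of a group differed by more than counting noise (chi-square per degree of freedom of 9.7 and 11.6 for genes, 586 and 380 for small RNA), so none was counted as a duplicate. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. For small RNA as deposited, limma's prior degrees of freedom were infinite. Each SE then came from the trend over all features, not from the feature's own spread.

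The alternatives were other pseudocounts (0.1 and 5), no filter and a stricter one (10 RPM, or 50 RPM for small RNA), median-ratio scaling, quantile normalization, eBayes without trend and with robust fitting, the replicate number as a block, edgeR, DESeq2, each library left out in turn (the lone library of a group is then assumed to vary like the other group), camera with an estimated correlation or with ranks, the most abundant small RNA left out, and let-7 features of at least 100 RPM only. Scaling to the reads in the rows, leaving out the microRNAs of other cell types, and leaving CDCA8 out of the chromosomal passenger complex list were added after the data were seen. Genes were placed in order with the RefSeq annotation of GRCh38.p14, used only to tell which genes neighbour each other, since the build of the values is hg19. Of 11833 kept genes, 11619 (98.2%) had a place. The SD of fold changes was taken over every part of the run that holds its highest window of 15 genes and set against all stretches as long. That of the window was also set against the highest window of each of 1000 shuffles.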

Results

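Expression was measured in C4-2 cells, an established human prostate cancer line derived from LNCaP that grows without added androgen. In the RNA sequencing, 2 control libraries (shCTRL) were set against 2 libraries of cells with a hairpin against CDCA8, which encodes borealin, a subunit of the chromosomal passenger complex that guides chromosome segregation. In the small RNA sequencing, 2 shCTRL libraries were set against 2 libraries of cells with a hairpin against EZH2, the histone methyltransferase of Polycomb repressive complex 2. The RPM divisors corresponded to 53305010 and 46709612 reads in the shCTRL and 52248230 and 55289855 reads in the shCDCA8 RNA libraries, of which 21920570, 20380764, 17406425 and 18931009 reads fell in the gene rows. In the small RNA libraries they were 37471354 and 32666731 reads for shCTRL and 36973498 and 39498220 reads for shEZH2, of which 4064692, 4582403, 6765539 and 5980595 reads fell in the microRNA rows.

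The RNA sequencing addressed which genes depend on CDCA8 in these cells. The sample titles name no second hairpin or rescue, so effects of the hairpin outside CDCA8 cannot be told apart from loss of CDCA8. CDCA8 itself stood at 14.2 and 16.5 RPM in the shCTRL libraries and at 3.98 and 3.94 RPM in the shCDCA8 libraries, a log2 fold change of -1.72 ± 0.135 (SE, n = 2 against 2, limma adjusted p = 7.86e-07). The other 3 genes of the chromosomal passenger complex fell with it. BIRC5, which encodes survivin, went from 45.7 ± 1.35 to 14.5 ± 0.818 RPM (SD, n = 2). AURKB, the kinase of the complex, went from 11.9 ± 0.435 to 3.88 ± 0.371 RPM. INCENP, its scaffold, went from 13.4 ± 1.08 to 6.86 ± 1.25 RPM. EZH2 (log2 fold change -1.52) and the cell cycle transcription factor E2F1 (-1.60) also fell.

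**Figure D1:**
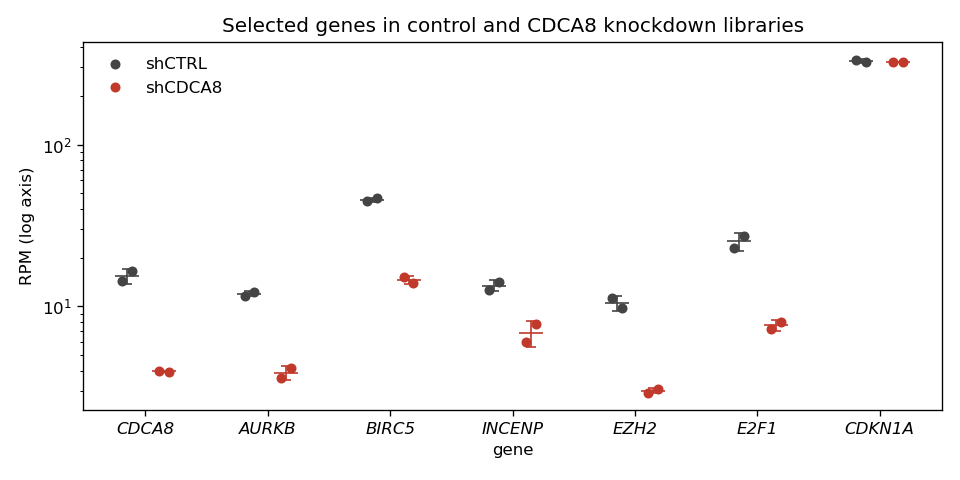
RPM on a log axis for 7 genes in the 2 shCTRL (grey) and 2 shCDCA8 (red) libraries, each point a library, with the mean and SD. CDCA8 lies at 14.2 and 16.5 RPM in the controls and 3.98 and 3.94 RPM after knockdown, while CDKN1A lies between 323 and 335 RPM in all 4 libraries; CDKN1A is higher after knockdown under median-ratio scaling.

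Beyond the target, the ATF4 target genes, genes of the cell cycle and genes of the cytosolic ribosome were lower after CDCA8 knockdown, and nuclear genes of mitochondrial respiration were higher. Each of these lists passed camera, and none did with an estimated correlation (adjusted p = 0.581). With 2 libraries per group the latter setting has little power. It gave the same adjusted p for each of these lists, so it cannot decide whether they hold. ATF4 is the transcription factor of the amino acid and integrated stress response, and all 23 measured genes of its list, its own among them, fell, with a median log2 fold change of -2.34. Of 40 DNA replication and E2F targets 35 fell (median -0.82), and of 50 oxidative phosphorylation genes 32 rose and 2 fell (median 0.31). In all, 7852 of 11833 genes were called (66.4%), 2224 of them higher and 5628 lower, and 2104 changed at least 2-fold, 378 upward and 1726 downward (791 upward and 1004 downward under median-ratio scaling). The groups did not overlap for 9850 genes (83.2%), where chance gives 33.3%. A shift of the whole table can raise this share. It was 63.5% for the small RNA features, of which 4 of 241 were called.

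The whole table was shifted: the median log2 fold change over kept genes was -0.27, and the gene rows took 41.1% and 43.6% of the divisor in the controls but 33.3% and 34.2% after knockdown. With median-ratio scaling, which removes this shift, 7910 genes were called, 3931 higher and 3979 lower, so the share of higher calls went from 28.3% to 49.7%. The split was 3980 against 3721 with quantile normalization, 3851 against 3956 with edgeR, 3639 against 3575 with DESeq2, and 3957 against 3849 with scaling to the reads in the rows.

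The ATF4 list held the lowest median of the 19 tested lists. PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, fell from 170 ± 16.4 to 10.7 ± 0.993 RPM (log2 fold change -3.87 ± 0.116, adjusted p = 1.23e-09). NUPR1, a stress-induced chromatin protein, fell by 3.25 on the log2 scale, and PSAT1, an enzyme of serine synthesis, by 2.97. CHAC1, which degrades glutathione, fell from 45.1 ± 0.474 to 2.52 ± 0.627 RPM. The list passed camera with an adjusted p of 3.47e-11, and all 23 genes fell both when adjusted over the list alone and under median-ratio scaling (median -2.04). Its camera adjusted p was 0.581 with an estimated correlation.

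KLK3, which encodes prostate-specific antigen, fell from 1465 ± 15.9 to 401 ± 52.2 RPM (-1.87 ± 0.0957). SLC45A3, a prostate-enriched transporter, had the largest fall of all genes under the rule, from 148 ± 11.6 to 9.14 ± 0.831 RPM (-3.87), and C1orf116 fell by 2.54 on the log2 scale.

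Of 36 measured mitotic genes, 27 fell and none rose (median -0.66). FOXM1, a mitotic transcription factor, fell by 1.86, CDC20, an activator of the anaphase-promoting complex, by 1.80 and RACGAP1, a cytokinesis factor, by 1.67 on the log2 scale. Among the replication and E2F targets, the helicase subunit MCM3 fell by 1.84 and the thymidine kinase TK1 by 1.28. The counts adjusted over the list alone were 27 for mitosis, 36 for replication and 4 of 4 for the chromosomal passenger complex (median -1.50), and with median-ratio scaling 20 mitotic genes fell and 3 rose, 26 replication genes fell, and the 4 complex genes fell. Camera gave adjusted p of 0.00328, 8.22e-05 and 0.0364 for the 3 lists. Each had an adjusted p of 0.581 with an estimated correlation. The passenger complex list holds CDCA8, the target of the hairpin, and its other 3 genes alone did not pass (median relative to all kept genes -1.14, adjusted p = 0.0912).

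Cytosolic ribosomal protein genes moved opposite to those of respiration. Of 72 ribosomal genes 68 fell (68 adjusted over the list alone), with a median of -0.62, among them RPL10 (-1.22), RPL28 (-1.01) and RPL29 (-0.98), although reads of such genes can be shared with their many processed pseudogenes. Under median-ratio scaling 48 fell and 2 rose. Of the oxidative phosphorylation genes, UQCRC2 of complex III rose from 78.0 ± 7.35 to 136 ± 1.19 RPM (0.80), SDHA of complex II by 0.71 and NDUFB3 of complex I by 0.90. Adjusted over the list alone 32 rose, and 46 rose and 1 fell under median-ratio scaling. Camera gave adjusted p of 5.78e-09 for the ribosomal and 2.04e-10 for the respiration list. Both had an adjusted p of 0.581 with an estimated correlation.

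The 6 lists above passed camera at the preset correlation, as did 1 list that is not described. None of the 7 held with an estimated correlation, which has little power with 2 libraries per group. The passenger complex list did not pass without CDCA8.

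**Figure D2:**
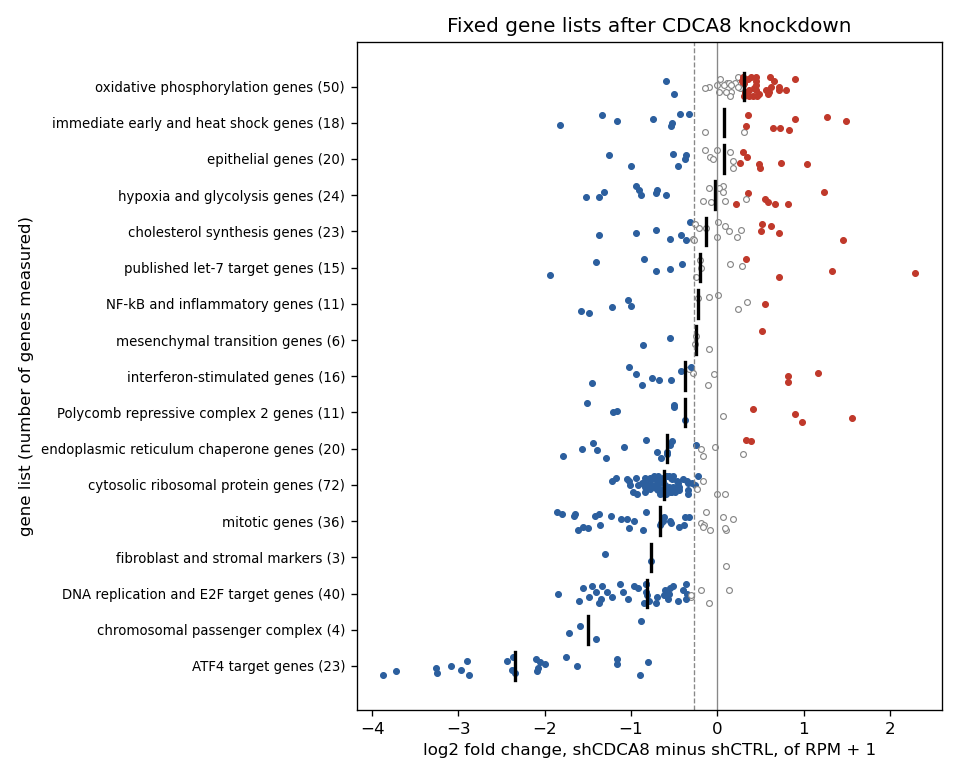
Log2 fold change (shCDCA8 minus shCTRL, RPM + 1) of each measured member of 17 tested gene lists, 1 point per gene; red points rose, blue fell, open points were not called, black bars are list medians and the dashed line is the median of all kept genes, -0.27. All 23 genes of the ATF4 list, ATF4 among them, lie below 0 and 32 of the 50 oxidative phosphorylation genes are red. Colours are from the deposited values, tested against 0. Under median-ratio scaling, which is not drawn, 46 respiration genes rose, and 48 ribosomal genes fell against 68 as deposited.

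Of 20 endoplasmic reticulum chaperone genes 14 fell and 2 rose (camera adjusted p = 0.0624, between 0.00247 and 0.581 over the alternatives; 11 fell and 3 rose under median-ratio scaling), with XBP1 (-1.79), HERPUD1 (-1.57) and HYOU1 (-1.40) lowest in p. That list was under the threshold in 8 of 18 alternatives, among them without shCTRL replicate 2 (median relative to all kept genes -0.34, adjusted p = 0.0215) and without shCDCA8 replicate 1 (-0.43, adjusted p = 0.00247). GDF15 fell from 585 ± 20.9 to 202 ± 8.02 RPM, TNFRSF10B fell by 0.99, and ZMAT3 rose from 16.7 ± 2.00 to 52.6 ± 3.52 RPM. CDKN1A, the cell cycle inhibitor p21, was not called (329 ± 8.33 against 323 ± 0.213 RPM, log2 fold change -0.03, adjusted p = 0.802), and under median-ratio scaling it was higher by 0.29 (adjusted p = 0.0113, between 0.000634 and 1 over the alternatives).

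Of 23 cholesterol synthesis genes 7 fell and 5 rose (adjusted p = 0.33), and 3 fell and 11 rose under median-ratio scaling, with TM7SF2 up by 1.46, DHCR7 at -1.37 and INSIG1 at -0.94. Of 24 hypoxia and glycolysis genes 9 fell and 7 rose (adjusted p = 0.479; 9 and 13 under median-ratio scaling), with VEGFA (-1.32), HK2 (-1.52) and SLC2A1 (-1.37) among those that fell. Of 16 interferon-stimulated genes 9 fell and 3 rose (adjusted p = 0.829; 6 and 3 under median-ratio scaling): ISG20 (-1.45) and IFI6 (-1.02) fell. Of 11 NF-kB and inflammatory genes 5 fell and 1 rose (adjusted p = 0.733; 5 and 4 under median-ratio scaling), with CD83 (-1.49) and TNFAIP2 (-1.59) falling and TNIP1 going from 66.5 ± 0.435 to 32.7 ± 0.692 RPM. Relative to all kept genes the NF-kB list had a median of 0.04 and a mean of -0.21.

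Of 18 immediate early and heat shock genes, a list that also reflects handling stress, 8 rose and 8 fell (adjusted p = 0.152; 9 and 5 under median-ratio scaling). MYC fell from 146 ± 9.76 to 57.2 ± 3.08 RPM, IER3 fell by 1.83 and IER2 rose by 1.28. Of 11 Polycomb repressive complex 2 genes 6 fell and 4 rose (adjusted p = 0.758; 3 and 5 under median-ratio scaling), EZH2 with its cofactors JARID2 (-1.16) and PHF19 (-1.21) among the falls. Relative to all kept genes the Polycomb list's median was -0.11 and its mean 0.17, and camera pointed upward. Of 15 published let-7 targets 6 fell and 4 rose (camera adjusted p = 0.55, between 0.0339 and 0.879 over the alternatives). Under median-ratio scaling 4 fell and 6 rose. That list passed in 1 of 18 alternatives, and its median relative to all kept genes, 0.07 as deposited, went from -0.10 to 0.75 over them. HMGA1 (-1.94) and IGF1R (-1.41) fell, and DICER1, the nuclease that cuts microRNA precursors, rose from 8.23 ± 1.68 to 44.0 ± 3.82 RPM.

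Of 20 epithelial genes 7 rose and 6 fell (adjusted p = 0.109), with ELF3 (1.04) and KRT8 (0.74) up and CLDN3 down (-1.25). Under median-ratio scaling 12 rose and 3 fell and that list passed (adjusted p = 0.0446, between 0.0344 and 0.581 over the alternatives). Of 6 mesenchymal transition genes TAGLN rose (0.52), VIM (-0.86) and TPM1 (-0.55) fell (adjusted p = 0.854; 1 rose and 1 fell under median-ratio scaling), and TPM1 was no longer called under median-ratio scaling (adjusted p = 0.0569, between 4.37e-07 and 0.0764 over the alternatives), nor TAGLN without shCTRL replicate 1 (0.27, adjusted p = 0.154). The mesenchymal list had a relative median of 0.02 and mean of 0.04 where camera pointed downward.

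Markers of other cell types were few. Of 3 measured fibroblast markers 2 fell (COL1A1 -1.30; adjusted p = 0.585), of 2 basal markers ITGB4 fell (-1.49), of 2 leukocyte and endothelial markers VWF fell (-1.40) and 1 rose, and of 2 neuroendocrine genes DLL3 fell (-0.89) and 1 rose, with the same counts in these 4 lists under median-ratio scaling. No mitochondrially encoded gene was matched, so that list was not analysed here.

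The largest rises were of TINAGL1, a matrix protein gene that went from 0.794 ± 0.0882 to 32.8 ± 0.825 RPM (log2 fold change 4.24 ± 0.132, adjusted p = 1.45e-09), NKAIN1 (3.55), BAI2 (3.20), the membrane protein gene SERINC2, from 114 ± 3.05 to 879 ± 14.2 RPM (2.93), ZCCHC17 (2.69), the deubiquitinase gene YOD1 (2.33), DICER1 (2.30), COL16A1 (2.23), NARF (2.21) and TOMM34 (2.03). They are the largest among calls that meet the rule for named genes, with a mean of at least 5 RPM, as are the falls below. In RefSeq gene order (GRCh38.p14), 6 of these 10 genes lie in a single stretch of neighbouring genes. The largest falls, beside SLC45A3, PCK2 and CHAC1, were of the glycine transporter SLC6A9 (-3.79), TSC22D3 (-3.77), the neutral amino acid transporters SLC1A4 (-3.65) and SLC1A5 (-3.65), BEST1 (-3.53), ADM2 (-3.43) and MAP1B (-3.34).

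The small RNA sequencing addressed which microRNAs depend on EZH2. Small RNA libraries do not measure EZH2 mRNA, so the knockdown could not be checked as that of CDCA8 was. Effects of the hairpin outside EZH2 could not be told apart from loss of EZH2. All 13 measured features of the let-7 family, tumour-suppressive microRNAs, had a higher mean RPM after EZH2 knockdown, but 197 of all 241 features (81.7%) did, and no let-7 feature passed the test (limma, with 1 at an unadjusted p under 0.05 and 0 calls by edgeR or DESeq2). The family's median log2 fold change was 0.54, or 0.11 above the median of all features (0.43). Between the shCTRL libraries, replicate 2 minus replicate 1, the family's median differed more, by 0.23 relative to all features. let-7b-5p went from 15090 ± 3491 to 22790 ± 2084 RPM (adjusted p = 0.397), let-7a-5p from 15170 ± 2680 to 21420 ± 3956 RPM (adjusted p = 0.437), let-7c-5p from 12320 ± 3790 to 17530 ± 1013 RPM (adjusted p = 0.404), and let-7i-5p from 1719 ± 302 to 2823 ± 431 RPM (adjusted p = 0.316). The other members had log2 fold changes between 0.39 (let-7a-3p) and 0.89 (let-7b-3p). The list had a camera p of 0.0476 unadjusted and 0.185 adjusted over 12 lists (unadjusted p = 0.562 with an estimated correlation), and an adjusted p of 0.0298 with median-ratio scaling, where its median was 0.17 (adjusted p between 6.47e-05 and 0.976 over the alternatives). Without shCTRL replicate 1 the median was 0.32, without shEZH2 replicate 2 it was 0.69, and neither passed even unadjusted, whereas without shCTRL replicate 2 the list passed, at 0.25 above all features (adjusted p = 0.006). All 13 log2 fold changes stayed above 0 under median-ratio scaling, with 0 calls. Quantile normalization turned let-7a-5p to -0.03, and scaling to the reads in the rows turned let-7a-3p to -0.0044. All let-7 rows together held 37.6% and 40.1% of the reads in the microRNA rows in shCTRL and 42.1% and 42.9% in shEZH2. This share was not tested.

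In all, 4 of 241 features were called, and 35 had an unadjusted p under 0.05. miR-182-5p, of a cluster often raised in cancer, rose from 555 ± 455 to 1416 ± 128 RPM (log2 fold change 1.64 ± 0.360, adjusted p = 0.000774). miR-143-3p, typical of smooth muscle, rose from 18.2 ± 5.98 to 65.7 ± 0.515 RPM (1.83 ± 0.378, adjusted p = 0.00041). miR-122-5p, typical of liver, rose from 23.6 ± 18.0 to 79.8 ± 88.2 RPM (1.28 ± 0.379, adjusted p = 0.0457), and miR-486-5p, typical of red blood cells, fell from 54.2 ± 58.1 to 10.5 ± 0.156 RPM (-1.68 ± 0.383, adjusted p = 0.00112). The last 3 were among 6 measured microRNAs fixed beforehand as markers of other cell types. The groups overlapped for miR-122-5p, at 36.3 and 10.9 RPM in shCTRL and 142 and 17.4 RPM in shEZH2. Its SE came from the trend over all features, so this spread had no weight of its own in the call. None of the 4 was called under median-ratio scaling, quantile normalization, edgeR or without the filter. DESeq2 called miR-143-3p (adjusted p = 3.19e-05) and miR-486-5p (adjusted p = 0.0151) and not the others. Each lost its call when some single library was left out. Without shCTRL replicate 2, miR-182-5p stood at 0.69, miR-122-5p at 0.46 and miR-486-5p at -0.30, and without shCTRL replicate 1 at 2.60, 2.11 and -3.07. Without shEZH2 replicate 1 miR-122-5p stood at -0.19 and without shEZH2 replicate 2 at 2.76. miR-143-3p stood between 1.51 and 2.16 with each library left out, and was not called without shCTRL replicate 1 (1.51, adjusted p = 0.0883).

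**Figure D3:**
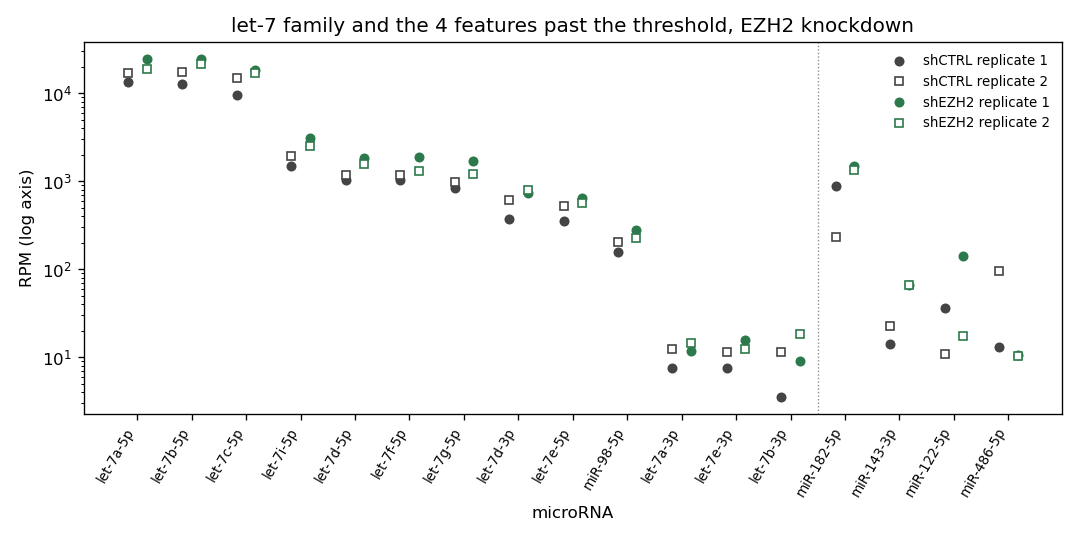
RPM on a log axis of the 13 measured let-7 features and, right of the dotted line, the 4 called microRNAs, with filled circles for replicate 1 and open squares for replicate 2 of shCTRL (grey) and shEZH2 (green). The let-7 means are higher after knockdown as deposited and under median-ratio scaling, and none passed. With quantile normalization let-7a-5p is not higher, and with scaling to the reads in the rows let-7a-3p is not. miR-122-5p reaches 142 RPM in a single shEZH2 library and miR-486-5p 95.3 RPM in a single shCTRL library.

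Among features that were not called, miR-345-5p stood at 803 ± 227 RPM in shCTRL and 397 ± 60.7 RPM in shEZH2 (adjusted p = 0.23), miR-200b-5p at 149 ± 6.27 and 76.6 ± 9.50 RPM (adjusted p = 0.269), miR-378a-3p at 2830 ± 27.5 and 1718 ± 200 RPM (adjusted p = 0.316), and miR-1307-3p at 1319 ± 114 and 884 ± 8.14 RPM (adjusted p = 0.397). These 4 were called lower by DESeq2, which called 11 features, 1 higher and 10 lower, 2 of them shared with limma. Without shCTRL replicate 2, miR-345-5p (-1.29, adjusted p = 0.0316) was also called by limma. miR-1268a had a log2 fold change of -0.70 (adjusted p = 0.316). In the other direction miR-574-5p (0.94), miR-221-3p (0.90), miR-342-3p (0.85) and miR-4521 (0.82) had adjusted p between 0.27 and 0.295. The most abundant microRNAs outside let-7 were miR-99a-5p, at 14180 ± 1570 and 18550 ± 3303 RPM, and miR-200c-3p, at 7832 ± 1606 and 9980 ± 15.8 RPM, neither called, and both were slightly below 0 under median-ratio scaling (-0.02 and -0.03).

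No microRNA list passed camera as deposited, though let-7 and the 5 measured miR-30 features passed with median-ratio scaling. The miR-30 family had a median 0.46 above that of all features (adjusted p = 0.094, and 0.0168 with median-ratio scaling, between 1.09e-05 and 0.976 over the alternatives), with 4 of its features higher when adjusted over the list alone and 0 over all features, miR-30c-5p standing at 10.7 ± 2.91 and 21.6 ± 1.02 RPM. The cluster of miR-183, miR-96 and miR-182 had 4 measured features, of which 1 rose (adjusted p = 0.094). It passed in 3 of 20 alternatives, and without shCTRL replicate 1 its relative median went from 0.22 to 0.34. The cluster of miR-221 and miR-222 had 3 features, 1 of them higher adjusted over the list alone (camera adjusted p = 0.185, between 0.038 and 0.976 over the alternatives). It passed in 2 of 19 alternatives, and its relative median went from 0.34 as deposited up to 0.71. No feature was called in 8 miR-200 family features (adjusted p = 0.682), 14 published Polycomb-repressed features (0.665; miR-125b-5p had a log2 fold change of 0.83, and 1.28 with adjusted p = 0.0211 without shCTRL replicate 2), 10 features of miR-17-92 (0.801; miR-92a-1-5p 0.75), 10 of miR-15/16 (0.665; miR-16-2-3p 0.67), 6 of miR-29 (0.964; miR-29a-3p 0.65), 5 of miR-23/27/24 (0.801; miR-23b-3p 0.62) and 8 androgen-responsive features (0.801). Of 6 microRNAs of other cell types 2 rose and 1 fell (adjusted p = 0.964). Published EZH2-targeting microRNAs had 2 measured features (miR-26b-5p 0.58) and the miR-34 family 1 (miR-34a-5p 0.55), too few to test, and the 14q32 and chromosome 19 clusters had 0 features past the filter. Relative to all features the median and mean differed in sign for miR-200 (0.06 and -0.13), miR-17-92 (-0.02 and 0.06) and miR-23/27/24 (-0.02 and 0.07). With an estimated correlation, which has little power with 2 libraries per group, all 12 lists had a camera adjusted p of 0.976.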

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

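The share of the RPM divisor that fell outside the gene rows was higher in both CDCA8 knockdown libraries than in either control, and these reads enter the gene comparisons above only through the divisor. It was 66.7% in shCDCA8 replicate 1 and 65.8% in shCDCA8 replicate 2, against 58.9% and 56.4% in shCTRL replicates 1 and 2. The reads outside the rows analysed here were not examined, and the difference was not tested.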

How the results depend on the processing

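Scaling to the reads in the rows, leaving out the microRNAs of other cell types and leaving CDCA8 out of the chromosomal passenger complex list were chosen after the data were seen. The cause of a change was not tested except where the construction shows it (fewer genes tested, fewer libraries). CDCA8 was called in every alternative (-1.93 to -1.18), and the mRNA call count stayed within 1.5 times except under the stricter filter, which tests fewer genes: 4704 called, 1434 higher, 3270 lower and 1288 changed at least 2-fold. A pseudocount of 5 left 849 genes at 2-fold or more. Higher calls went to 3931 with median-ratio scaling, 3980 with quantile normalization (3721 lower), 3851 with edgeR, 3639 with DESeq2 (3575 lower) and 3957 with scaling to the reads in the rows. CDKN1A turned to 0.29, 0.38, 0.28, 0.29 and 0.30 in those 5. With an estimated correlation 0 of 7 mRNA lists held (limma's camera; 19 lists tested).

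With the replicate block 8901 genes were called, and 2 small RNA features (1 higher, both at least 2-fold). Same-numbered libraries deviated together with a correlation across genes of 0.313 (mRNA) and 0.317 (small RNA), but share only a number. The let-7 median was 0.54 under the block, with an unadjusted camera p of 0.174.

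Small RNA calls went from 4 to 0, in either direction and at 2-fold, with no filter, median-ratio scaling, quantile normalization, edgeR and scaling to the rows (78, 32, 35, 26 and 32 at an unadjusted p under 0.05). They were 2 with the stricter filter (0 lower, 2 at 2-fold), 1 with robust eBayes (1 higher, 0 lower, 1 at 2-fold), 11 with DESeq2 (1 higher, 10 lower, 7 at 2-fold) and 1 without microRNAs of other cell types (1 higher, 0 lower, 1 at 2-fold). Leaving out each library gave 4 to 6 calls, 2 to 5 higher and 1 to 2 lower. Passing microRNA lists went from 0 to 3 with no filter, 2 with median-ratio scaling, 3 with quantile normalization, 1 with edgeR, 1 with DESeq2, 3 with scaling to the reads in the rows, 2 without microRNAs of other cell types, 1 with ranks and 0 to 1 without each library. The let-7 median stayed above 0 but lost an unadjusted camera p under 0.05 at pseudocount 5 (0.54), with the stricter filter (0.58), without let-7b-5p (0.55), with an estimated correlation (0.54), at 100 RPM or more (0.58), without shCTRL replicate 1 (0.32) and without shEZH2 replicate 2 (0.69). Without shCTRL replicate 2 (0.79) and without shEZH2 replicate 1 (0.48) it stayed under 0.05.

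The other sign changes were in results not called as deposited, apart from miR-122-5p (-0.19 to 2.76 over the libraries left out). miR-99a-5p turned to -0.018 (median-ratio), -0.15 (quantile), -0.018 (DESeq2) and -0.052 (rows), miR-200c-3p to -0.033 (median-ratio), -0.011 (edgeR), -0.029 (DESeq2) and -0.067 (rows), miR-26b-5p to -0.085 and let-7a-5p to -0.033 (quantile), and let-7a-3p to -0.0044 (rows). List medians relative to all features changed sign as follows. NF-kB: -0.12 (pseudocount 0.1), -0.080 (median-ratio), -0.16 (edgeR), -0.16 (DESeq2) and -0.12 (rows). Mesenchymal: -0.016 (pseudocount 0.1), -0.014 (median-ratio), -0.024 (edgeR), -0.024 (DESeq2), -0.020 (rows) and -0.017 to 0.053 over libraries left out. A list not described: -0.030 (pseudocount 5), -0.14 (no filter), -0.042 (stricter), -0.030 (quantile) and -0.057 to 0.094. Interferon: 0.0055 (no filter) and 0.13 (stricter). let-7 targets: -0.10 (no filter) and -0.026 to 0.082. Fibroblast: 0.057 (no filter). miR-23/27/24: 0.037 (pseudocount 5), 0.34 (no filter), 0.12 (quantile) and -0.11 to 0.081. miR-17-92: 0.27 (no filter), 0.00010 (quantile) and -0.11 to 0.046. Androgen-responsive: -0.087 (stricter) and -0.15 (quantile). Polycomb-repressed: -0.0082 (quantile) and -0.0096 to 0.099. Other cell types: -0.0026 (quantile) and -0.31 to 0.23. miR-15/16: -0.032 to 0.18. Of the other comparisons of a named gene or list with an alternative, 2353 stayed on their side of the threshold, 46 lost a call and 38 gained one; the median of all kept genes moved in 6 alternatives.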

Other observations

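All tests below were chosen after the result was seen, except the bound for the 20 cytosolic aminoacyl-tRNA synthetase genes, which was set before their values were looked at; the genes named here were likewise chosen after their values were seen.

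A stretch of 34 neighbouring measured genes was higher after CDCA8 knockdown: 27 of them rose and 3 fell, where 18.8% of all measured genes rose, and 28 rose under median-ratio scaling. A high share of rises follows from how the stretch was bounded. It holds the genes around the highest window whose own centred window of 15 had a median at least 0.5 above that of all genes. It runs in RefSeq order (GRCh38.p14) from SRSF4 to ZBTB8A and holds LAPTM5 (0.263 and 0.235 RPM in shCTRL, 6.83 and 5.50 RPM in shCDCA8), SDC3 (1.67), NKAIN1 (3.55), ZCCHC17 (2.69), SERINC2 (2.93), TINAGL1 (4.24), COL16A1 (2.23), BAI2 (3.20), PTP4A2 (1.91) and KPNA6 (1.32; log2 fold changes), with smaller rises of SNRNP40 (0.55) and HDAC1 (0.38). Elsewhere PDCD1, the immune checkpoint receptor, had 1 and 0 reads in the shCTRL libraries and 515 and 502 in the shCDCA8 libraries (9.86 and 9.08 RPM), and of its 9 measured neighbours ATG4B, DTYMK, ING5, NEU4 and RTP5 rose, by 0.84 to 1.81 relative to the median of all genes. BOK fell (-0.58), and THAP4, D2HGDH and GAL3ST2 were not called.

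The cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, split after CDCA8 knockdown: 9 of 20 fell and 4 rose, and 9 fell and 11 rose under median-ratio scaling. GARS fell from 247 and 257 to 64.2 and 62.5 RPM, CARS fell by 1.56, WARS by 1.27, MARS by 1.22, SARS by 1.21 and YARS by 1.20 on the log2 scale, while RARS rose by 0.99. Of 17 mitochondrial synthetase genes 7 fell and none rose (3 fell and 7 rose under median-ratio scaling; limma), and their median lay 0.11 above that of all genes.

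The tables argue against chance order for the run of neighbours: its highest median over 15 genes, 2.18 above all genes, was reached in 0 of 1000 shuffles of the gene order (highest 1.12; permutation p = 0.000999, the smallest they can give). They argue against the scaling: the whole table shifted downward (median -0.27), and the run's median was 0.76 as deposited and 1.01 under median-ratio scaling. They do not decide on 1 uniform gain in copy number: fold changes in the run went from -1.05 to 4.24 with an SD of 1.21, against a median SD of 0.68 for stretches as long, and the SD of every part that holds the highest window lay at or above the 99.2nd percentile of such stretches, but that of the window lay at the 96.9th percentile of the highest windows of the shuffles, short of the bound of 99. Such a gain, a gain with uneven effects, an insertion near the most raised genes, or a local change in regulation in the knockdown cells may each account for it, and without DNA data these remain open.

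For the 23 genes of the ATF4 list, which holds ATF4 itself, the tables argue against the scaling: the whole table shifted by only -0.27 (median). The list's median was -2.34 as deposited, and removing so small a shift could only leave it far below 0 (-2.04 under median-ratio scaling). The tables also argue against a difference of the kind that separates the control libraries, which was -0.0036 for this list relative to all genes. The hypothesis that the wider amino acid response fell was tested on synthetase genes outside the list, and the answer depended on which of them were taken. A first list of 12 cytosolic genes, picked as ones ATF4 is known to induce, had a median of -0.67 relative to all genes but did not pass (camera p = 0.0679, and 0.375 with an estimated correlation), and the full set of 20 had 0.31 (camera p = 0.949), above the bound set beforehand, so the tables argue against a fall across all synthetase genes and leave open a fall of those under ATF4. Both lists are given because the wider one was drawn up after the first, before either was measured. The bound for the list of 12 was set only after its values were seen. Each group may also have differed in medium or density when harvested, which the design does not separate from the knockdown.

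For the 4 called microRNAs, 1 deviating library fits miR-182-5p and miR-486-5p. Both, and miR-122-5p (3 of 3), differed more than 2-fold between libraries of the same group. But miR-122-5p did so in both groups (36.3 and 10.9 RPM in shCTRL, 142 and 17.4 RPM in shEZH2), which 1 library cannot give. The largest such log2 difference for miR-143-3p was 0.646, against a fold change of 1.83. RNA from other cells may account for miR-122-5p, miR-143-3p and miR-486-5p and stays open. miR-451a, the most abundant red blood cell microRNA, stood at 519, 3350, 917 and 1181 RPM and was high with miR-486-5p in shCTRL replicate 2. Outside that library miR-451a ranged from 519 to 1181 RPM while miR-486-5p stayed between 10.4 and 13.1 RPM. A red blood cell microRNA bears on miR-486-5p only, not on miR-122-5p or miR-143-3p. The scaling stays open too: under median-ratio scaling the median absolute fold change was 1.35 and no call by limma was left, but miR-486-5p went further, from -1.68 ± 0.383 to -2.05 ± 0.891 (SE), and DESeq2 called it (adjusted p = 0.0151) and miR-143-3p (adjusted p = 3.19e-05). For miR-143-3p the fold went from 1.83 ± 0.378 to 1.45 ± 0.219 (SE) and for miR-182-5p from 1.64 ± 0.360 to 1.25 ± 0.763, while limma's prior degrees of freedom fell from infinite to 2.17: the changed SE and degrees of freedom alone, at the deposited folds, left 0 of the 4 calls, and the changed folds alone ended only that of miR-122-5p (limma adjusted p = 0.394). No biological explanation was tested beyond the group difference itself.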
